A study of Mus musculus with 6 samples.

How the data were processed

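Single-cell RNA was measured in 6 libraries of mouse dorsal root ganglia from all segmental levels. Per the labels' protocols, ganglia were digested with papain, collagenase, hyaluronidase and DNase, triturated, passed through a mesh and washed, and libraries were made with the 10x Genomics Chromium single cell kit, version 3 chemistry, which captures 3′ ends of polyadenylated RNA. The deposited values are raw UMI counts per gene and barcode, whole numbers in 1 sparse matrix per library, limited by the authors to barcodes that passed a cell filter. Per the submitters' processing notes, Cell Ranger was used with the mouse build mm10; its version, annotation and settings are not given in the sources used here. The 28694 features include the transgenes Cre and Tdtomato beside mouse genes. The replicate numbers of the labels did not separate the libraries, the genotype label is the same in all 6, and the title names mutants and controls, so all 6 stayed without a group. No genotype was inferred from Piezo2, Cre, Tdtomato, sex-linked genes or order. No library was a copy of another: the mean chi-square per gene between 2 libraries was 25.8 to 330, where sampling noise alone gives about 1. That value cannot tell whether libraries came from the same animals.

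Barcodes were kept with 1000 or more detected genes and at most 10% mitochondrial UMIs, which 45579 of 92895 passed. Doublets were scored per library with Scrublet in scanpy 1.11.5, at an expected rate of 8%. Its automatic threshold marked 0.0119% and 0.134% of cells in libraries 1 and 3, so a fixed score of 0.25 was used in all libraries after that was seen. It removed 1766 cells, 2.96 to 4.47% per library. Counts were scaled to 10000 per cell and log-transformed, 3000 variable genes were chosen across libraries, and each was centred and scaled within its library, a step added after the data were seen. Then followed 40 principal components, a graph of 15 neighbours and Leiden clustering (igraph 0.11.9, resolution 1). Genes of the report lists, Hox genes, mitochondrial genes and the transgenes took no part; list genes that are also markers entered the naming alone. A cluster was called neuronal when at least 8 of 15 neuron markers were each found in at least 50% of its cells. The neurons were clustered again at resolution 1.5 into 43 clusters.

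Marker lists, gene lists, comparisons and the rule for naming genes in the text were fixed before the data were examined, as were the alternatives given last, except where marked. The rule that scores clusters was revised after the clusters were seen. A class score was the mean log2 ratio of its markers in the cluster to the median over clusters, with 10 CPM added. A name needed a score of at least 0.5, at least 3 markers at 2-fold and in at least 5% of cells, no more markers of another class than its own among the 10 leading genes, and a margin of 0.3 over the next class; a shallow cluster also needed a marker among its leading genes. A-fibre and C-fibre peptidergic markers overlap and were merged to 1 class. Unnamed clusters held 14.5, 8.65, 9.45, 12.2, 7.90 and 8.24% of neurons in libraries 1 to 6. Those kept out by the margin alone were 4 of the 8 unnamed clusters, with 4.75, 2.5, 2.61, 2.71, 1.73 and 2.27% of neurons in libraries 1 to 6. Names built from markers can differ from the authors' own.

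Levels are UMIs of a gene summed over the cells of a class in 1 library, over all UMIs of those cells, in CPM, with exact Poisson intervals. Shares have exact Clopper-Pearson intervals, and ratios of 2 levels have exact conditional binomial intervals, all at 95% and for counting error only. A count of 0 stands for at most 3 counts, which is 0.0330 to 0.128 CPM over all neurons of a library. With no groups there was no test across libraries. Gene lists were compared by the 2-fold rule in each of the 6 libraries; the higher level needed more than 3 counts and the lower was set to at least 3, a floor added after the first run called Piezo1 higher where it had few counts. Scn2a, 1 of 44 voltage-gated and leak channel genes, had no feature of that name, so 43 were measured. The caudal to rostral ratio was a Mantel-Haenszel ratio over classes. Of the Hox genes, Hoxa11 and Hoxc11 had 0 UMIs in neurons, and 13 of 14 Hoxd10 and all 19 Hoxd11 UMIs were in library 6. Genes differing between libraries had a median of 20 CPM or more and a ratio of highest to lowest library of at least 4.

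Genes were named in the text by a fixed rule: Piezo2, Piezo1 and the level references; per class and list up to 3 higher members by the size of the smallest fold over libraries and up to 2 lower ones, at a median of 20 CPM or more; the 8 largest ratios between libraries over all neurons and 3 per LTMR class; and the 3 most abundant members of each state list. The text gives a part of these. Rgs5, Hbb-bs, Apoe, Fabp7 and Pmp22, which the rule would name as markers alone, are given for their level. Scn1a, Scn4b, Gabra3, Scn11a as a lower gene, Trpv1 and Oprm1 as higher genes of peptidergic-like cells and Ddx3y fall outside it and were chosen after their values were seen, as were the genes named for library 6 in the closing section.

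Gene positions, exons, introns and transcript sequences came from GENCODE M21, on the same build, and 28416 of 28694 features (99.0%) had an entry there. Near-identical copies were genes sharing at least 50% of the 31-base words in the last 300 bases of a transcript. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest. On simulated counts for 6370 genes over all neurons, the 4-fold rule between libraries called 50 of 50 genes made to differ 5-fold and 0 of 50 made to differ 2-fold, and in A-delta LTMR-like cells it also called 8 unchanged genes of 6357. The class rule called 40 of 40 genes made 3-fold higher and 35 of 40 made 3-fold lower in A-delta LTMR-like cells. A caudal to rostral ratio made 0.5 came back as 0.496 (0.490 to 0.511). That simulation took the caudal and rostral calls as true and drew counting noise alone. It therefore checks the arithmetic and not whether the data could show such a ratio. The other simulations also drew counting noise alone, from 1 profile shared by all libraries and classes. They leave out variation between cells and clusters, so the 8 unchanged genes do not estimate false calls in the data.

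The alternatives were: 500 or more genes with up to 20% mitochondrial UMIs; 2000 or more genes; no doublet removal; 0.5 and 1.5 times the resolution; equal weight per cell; thinning to 5000 UMIs, which left out 3208 of 5112 neurons in library 6 and between 616 and 2253 elsewhere; removal of a free RNA profile at 5%; other Hox rules; no strata; other sizes and minimum levels (1.5-, 2- and 3-fold; 5 and 50 CPM); and library totals scaled by the trimmed mean of M-values. Leaving out library 6 or library 1 and stratifying by cluster were added after seeing the data.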

Results

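The series profiled single cells dissociated from mouse dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, at postnatal days 21 to 24. Its title names littermates with and without a conditional Piezo2 mutation driven by Cdx2-Cre, a Cre line active in the caudal body. Piezo2 encodes the mechanically activated cation channel of touch receptors and proprioceptors. All 6 libraries carry 1 and the same wild-type genotype label, which the title contradicts, so none of them was assigned to a genotype and no mutant was compared with a control. The libraries are therefore numbered 1 to 6 and described side by side, as values per library or as a median and range. No p-value is given, and the 95% intervals are exact and cover counting error only.

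The matrices held 92895 cell barcodes and 476041301 unique molecular identifiers (UMIs, each counting 1 captured RNA molecule). Totals per library were 108823194, 82890019, 63964778, 109159076, 78532694 and 32671540 UMIs for libraries 1 to 6. Filtering left 43813 cells, of which 30864 were neurons, between 4563 and 6206 per library. The median depth of a neuron was 8791, 13902, 10235, 14740, 12098 and 4373 UMIs in libraries 1 to 6, so library 6 was the shallowest. Neurons made up a median of 73.5% of kept cells (range 52.5 to 93.1%), followed by satellite glia-like cells at 13.0% (3.92 to 24.8%) and endothelial-like cells at 8.30% (2.11 to 12.3%). Dissociation and the gene filter can set these shares.

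Most neurons resembled nociceptors, the neurons that detect noxious stimuli. Mrgprd nociceptor-like cells, which innervate skin, were a median of 32.0% of neurons (21.0 to 35.9%), and peptidergic-like cells, which release neuropeptides such as calcitonin gene-related peptide, were 28.2% (23.1 to 30.9%). C-LTMR-like cells, unmyelinated low-threshold mechanoreceptors (LTMRs) of hairy skin, were 11.7% (8.59 to 16.2%). The myelinated touch and position classes were rarer. A-beta LTMR-like cells made up 3.01% of neurons (2.17 to 5.18%), proprioceptor-like cells 2.43% (1.36 to 3.48%) and A-delta LTMR-like cells 1.1% (0.959 to 2.61%). Sst pruriceptor-like and Mrgpra3 pruriceptor-like cells, both itch classes, made up 6.98% (5.48 to 9.01%) and 2.63% (1.71 to 2.76%), and Trpm8 thermosensor-like cells, which respond to cold, 2.22% (1.35 to 4.5%). Clusters holding 9.05% of neurons (7.90 to 14.5%) met no class and stayed unnamed. Library 6 had the lowest Mrgprd nociceptor-like share, 21.0% (19.9 to 22.2%), and the highest C-LTMR-like share, 16.2% (15.2 to 17.3%).

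**Figure D1:**
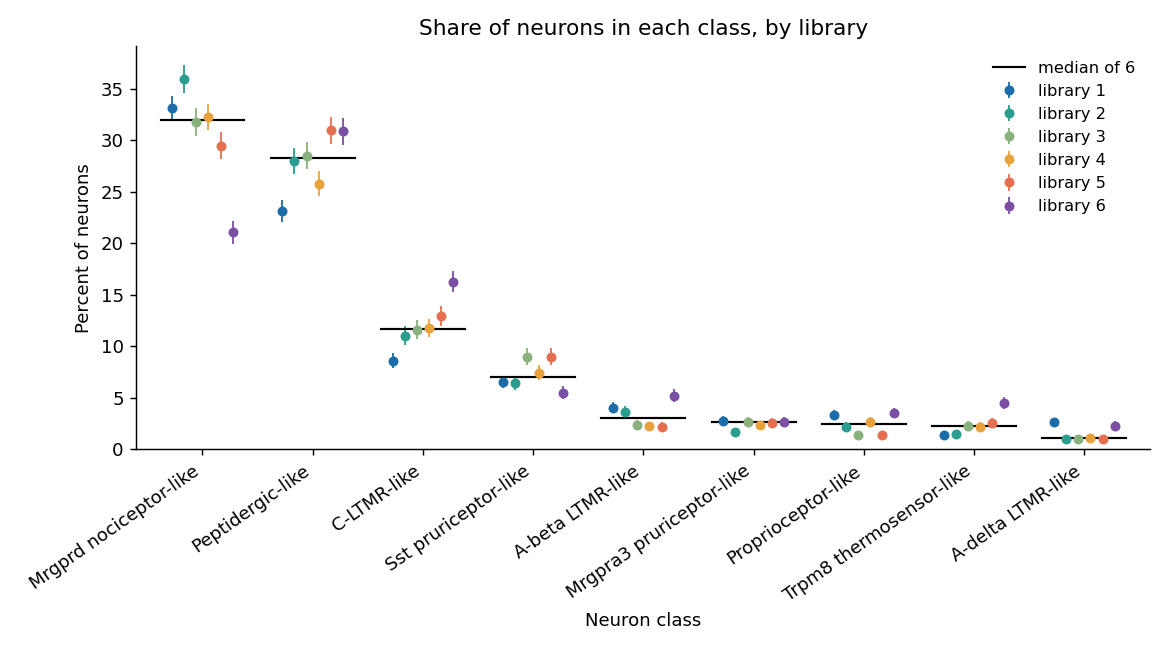
Share of neurons (percent, vertical axis) in each of the 9 named classes (horizontal axis), 1 point per library with its 95% exact binomial interval and a bar at the median of 6. Mrgprd nociceptor-like cells spanned 21.0 to 35.9% of neurons and A-delta LTMR-like cells 0.959 to 2.61%.

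Piezo2, identifier ENSMUSG00000041482, lies on the minus strand of chromosome 18 from 63010213 to 63387183 in the mm10 build, and its longest annotated exon chain has 54 exons. Over all neurons it reached 276, 284, 335, 337, 391 and 485 CPM (a gene's UMIs over all UMIs of the same cells, scaled to the usual total) in libraries 1 to 6. The kit captures the 3′ ends of transcripts, and a 3′ tag can lie outside the deleted part of a conditional allele, so these counts check no library's genotype.

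By median, Piezo2 was highest in the touch receptor classes and lowest in the cold-sensing class. C-LTMR-like cells held a median of 939 CPM (range 788 to 1181) and A-delta LTMR-like cells 862 (627 to 1076), followed by A-beta LTMR-like cells at 607 (512 to 621). Proprioceptor-like cells held 357 CPM (320 to 498) and Mrgprd nociceptor-like cells 328 (245 to 537), with the former higher in 5 of 6 libraries. A-beta LTMR-like cells also exceeded Mrgprd nociceptor-like cells in 5 of 6, and in library 6 they held 512 against 537 CPM. Levels were lower in Sst pruriceptor-like cells (129, 98.5 to 148), peptidergic-like cells (112, 97.2 to 194) and Mrgpra3 pruriceptor-like cells (69.8, 48.1 to 203). In Trpm8 thermosensor-like cells the level was 9.35 CPM (5.34 to 14.7), from 3 to 10 UMIs per library, and the intervals of the 6 libraries overlap. C-LTMR-like cells exceeded A-beta LTMR-like cells in each of the 6 libraries, by a median of 1.55-fold (1.30 to 2.31), and proprioceptor-like cells in each by 2.39-fold (2.02 to 3.69). Between C-LTMR-like and A-delta LTMR-like cells the order was not fixed: the former were higher in 4 of 6 libraries (median ratio 1.09, 0.928 to 1.35).

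In C-LTMR-like cells counting intervals were narrow next to the spread between libraries: Piezo2 was 788 CPM (769 to 808) in library 2 and 1181 CPM (1146 to 1216) in library 6. Different clusters held this class in different libraries: cluster 2 held 77.6% of it in library 6 and cluster 3 between 51.4% and 71.1% in the other 5. In library 1, cluster 1, found in no other library, held 70.4% of the A-delta LTMR-like cells. Library 1 also had the lowest Piezo2 level of this class, 627 CPM (591 to 664). Proprioceptor-like cells of library 1 and library 4 lay to 54.8% and 35.4% in cluster 7, which held 0.952% or less of them elsewhere. The A-beta LTMR-like clusters 30 and 39 were found in library 1 alone, with 10.7% and 9.92% of that class there.

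At least 1 Piezo2 UMI was found in a median of 97.4% of C-LTMR-like cells (91.9 to 99.2%) and in 5.31% of Trpm8 thermosensor-like cells (1.94 to 8.47%), whose median depths were 11108 and 4594 UMIs. With C-LTMR-like cells thinned to 5000 UMIs the first share was 97.9% (95.2 to 99.8%). Satellite glia-like cells, read here as a background for free RNA, held 32.4 CPM of Piezo2 (25.3 to 62.0). The Trpm8 thermosensor-like level lay below it and is not read as expression. Endothelial-like cells held 137 CPM of Piezo2 (125 to 164).

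Piezo1, the related channel of blood vessels and other non-neuronal cells, ENSMUSG00000014444 on chromosome 8 from 122481698 to 122551329 in mm10, was near zero in most neurons. It reached 57.9 CPM (29.4 to 77.0) in endothelial-like cells and 8.68 CPM (7.84 to 10.7) in Sst pruriceptor-like cells, against 0.815 CPM (0.650 to 1.02) over all neurons.

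**Figure D2:**
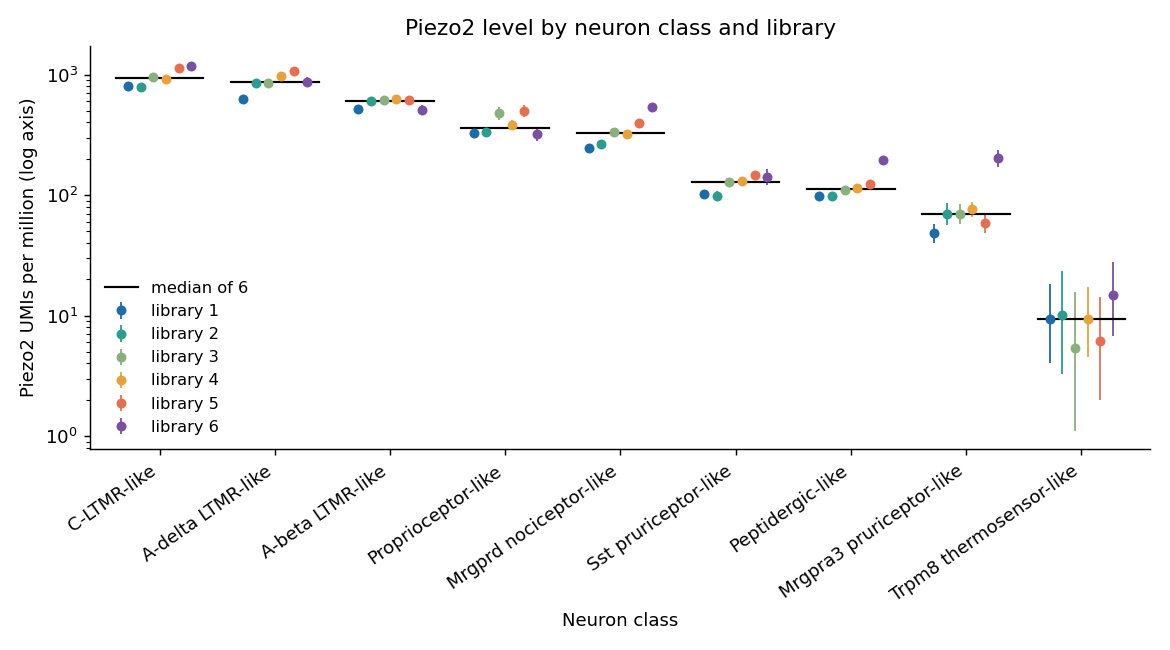
Piezo2 level (CPM, vertical log axis) in the 9 named neuron classes (horizontal axis), 1 point per library with its 95% exact Poisson interval and a bar at the median of 6. Medians run from 939 in C-LTMR-like cells to 9.35 in Trpm8 thermosensor-like cells.

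Ion channel and receptor genes were then compared across classes to show what else sets the touch neurons apart from the other sensory neurons. In 3 lists, 110 of the members were measured in 9 classes, which gave 990 pairs of gene and class. A gene counted as higher when its CPM in a class was at least 2-fold that of the pooled other classes in each of the 6 libraries, and as lower when it was at most 1/2 of theirs in each. By this rule of size, which is not a test, 140 pairs were higher and 276 lower. The myelinated classes held most of the higher pairs: 37 genes in A-beta LTMR-like, 26 in A-delta LTMR-like and 25 in proprioceptor-like cells, against 15 in peptidergic-like, 10 in C-LTMR-like and 8 in Mrgprd nociceptor-like cells. Mrgprd nociceptor-like cells had the most lower genes, 54 of 110. The floor of 3 counts is a higher level in smaller classes, so weak genes are called lower more easily in larger ones. The pooled others are weighted by UMIs, so the largest classes weigh most in them. These counts therefore do not rank the classes on an equal footing. The share of all measured genes that meet the rule is not given here. The counts thus do not show that channel and receptor genes differ more often than other genes. With each cell thinned to 5000 UMIs, which left too few Trpm8 thermosensor-like cells, the other 8 classes held 181 lower pairs.

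Of the 20 mechanotransduction genes, 9 pairs were higher and 33 lower among 180. Piezo2 met the rule for higher in C-LTMR-like cells alone, at 3.69-fold the other classes (3.35 to 3.95). A-delta LTMR-like cells did not meet it in all 6 libraries, though their median Piezo2 level was close, at 862 against 939 CPM. Piezo2 met the rule for lower in peptidergic-like, Sst pruriceptor-like, Mrgpra3 pruriceptor-like and Trpm8 thermosensor-like cells. No other member of this list was higher in any LTMR-like class or in proprioceptor-like cells. Kcnk2, a leak potassium channel gated by membrane stretch, was higher in peptidergic-like cells (148 CPM, 20.9-fold, 6.85 to 22.9) and Trpm8 thermosensor-like cells (228 CPM, 5.52-fold, 4.30 to 7.25), and lower in the other classes except Sst pruriceptor-like cells. Tmc7, of the transmembrane channel-like family, was higher in peptidergic-like cells (34.9 CPM, 11.6-fold, 8.29 to 15.4). Stom, encoding the membrane protein stomatin, was higher in Sst pruriceptor-like cells (55.4 CPM, 11.2-fold, 8.27 to 13.7). Trpa1, an irritant receptor, was higher in Mrgprd nociceptor-like cells (80.9 CPM, 2.75-fold, 2.61 to 3.17) and lower in all 3 LTMR-like classes and proprioceptor-like cells, with medians from 2.13 to 11.7 CPM.

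Among 43 measured voltage-gated and leak channel genes, 73 of 387 pairs were higher and 113 lower. Scn10a and Scn11a, the sodium channels of nociceptors that resist tetrodotoxin, were lower in the 3 LTMR-like classes and in proprioceptor-like and Trpm8 thermosensor-like cells. Scn10a, for example, had 19.6 CPM in A-beta LTMR-like cells (7.90 to 74.1) against 332 in the other classes. Scn1a, Scn8a and Scn4b, sodium channel subunits of fast myelinated axons, were higher in A-beta LTMR-like, A-delta LTMR-like and proprioceptor-like cells, with Scn8a at 451 CPM in the first (12.8-fold, 10.0 to 13.0). Of the potassium channel genes, Kcna1 reached 572 CPM in A-beta LTMR-like cells (22.3-fold, 11.1 to 24.8), Kcnq3 508 CPM in A-delta LTMR-like cells (26.6-fold, 16.2 to 34.3) and Kcnc1 175 CPM in proprioceptor-like cells (13.5-fold, 11.7 to 15.7), while Kcnd3 was lower in the last (7.83 against 89.6 CPM). Kcna1, Kcnq3 and Kcnc1 each met the rule for higher in A-beta LTMR-like, A-delta LTMR-like and proprioceptor-like cells alike. Kcnq3 met it in Mrgpra3 pruriceptor-like cells as well. Ano1, a calcium-activated chloride channel, was higher in proprioceptor-like cells (59.7 CPM, 99.2-fold, 37.0 to 165) and also met the rule in A-beta LTMR-like cells.

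C-LTMR-like cells had another set. Cacna1i, a T-type calcium channel gene, held 47.1 CPM there (40.7 to 52.1) against 0.167 CPM (0.0512 to 0.331) in the other classes. Kcnd3, of A-type potassium channels, was 9.17-fold higher (7.76 to 10.0) at 375 CPM. Cacna1h, also T-type, was higher in both C-LTMR-like (5.85-fold, 3.91 to 6.85) and A-delta LTMR-like cells (18.7-fold, 16.4 to 28.3). Kcns3, a modifier subunit of potassium channels, had 1.14 CPM in C-LTMR-like cells (0.499 to 4.79) against 33.5. In Mrgprd nociceptor-like cells 25 of the 43 genes were lower, while Scn11a (2.11-fold, 2.03 to 3.75) and Ano3 (2.89-fold, 2.59 to 3.49) were higher. Peptidergic-like cells were higher in the leak channel gene Kcnk3 (14.2-fold, 8.62 to 15.3) and in Cacna2d1, a calcium channel subunit bound by gabapentin (2.62-fold, 2.51 to 3.04). Kcnk3 also met the rule for higher in Trpm8 thermosensor-like cells.

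Among 47 ligand-gated channel and receptor genes, 58 of 423 pairs were higher and 130 lower. A-beta LTMR-like cells had 17 higher genes, among them the ATP-gated channel gene P2rx6 (41.1 CPM, 43.1-fold, 22.8 to 57.6) and the serotonin receptor genes Htr7 (39.7 CPM, 21.9-fold, 10.8 to 40.7) and Htr1d (117 CPM, 12.0-fold, 6.79 to 14.0). Htr1d was also higher in A-delta LTMR-like cells (162 CPM, 15.3-fold, 8.86 to 19.9), as was the metabotropic glutamate receptor gene Grm4 (70.9 CPM, 16.1-fold, 7.81 to 20.8). Asic1, an acid-sensing channel, was higher in proprioceptor-like cells (169 CPM, 27.2-fold, 15 to 33.6). Asic1, P2rx6, Htr7, Htr1d and Grm4 all met the rule in both A-beta LTMR-like and proprioceptor-like cells. Htr7 met it in A-delta LTMR-like and Grm4 in peptidergic-like cells as well. In C-LTMR-like cells the GABA receptor subunit genes Gabra2 and Gabra3 were among the higher genes, and 21 genes were lower. Gabra2 stood at 95.7 CPM (54.6 to 292). Over all neurons both were at least 4-fold higher in library 6 than the median of the others, Gabra2 at 131 against 29.1 CPM and Gabra3 at 20.2 against 2.5 CPM.

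In the same list Trpv1, the capsaicin and heat receptor, was higher in peptidergic-like cells and lower in the 3 LTMR-like classes, proprioceptor-like, Mrgprd nociceptor-like, Mrgpra3 pruriceptor-like and Trpm8 thermosensor-like cells; in A-beta LTMR-like cells it had 4.41 CPM (0.752 to 13.3) against 77.6 in the other classes. P2rx3, an ATP-gated channel of nociceptors, was higher in Mrgprd nociceptor-like cells (121 CPM, 5.24-fold, 4.80 to 7.60), with the kainate receptor gene Grik1 (167 CPM, 8.21-fold, 7.59 to 8.89). Npy1r, a neuropeptide Y receptor, was higher in peptidergic-like cells (95.9 CPM, 45.4-fold, 10.3 to 57.7), and Npy2r, another, in Sst pruriceptor-like cells (473 CPM, 49.1-fold, 31.8 to 61.4). Oprm1, the mu-opioid receptor, was higher in peptidergic-like cells and in Sst pruriceptor-like (3.11-fold, 2.79 to 3.5) and Trpm8 thermosensor-like cells (62.6 CPM, 4.51-fold, 3.30 to 7.01). Library 6 alone set the lowest fold given for Kcnk2 and Npy1r in peptidergic-like, Kcna1 in A-beta LTMR-like and Npy2r in Sst pruriceptor-like cells, and the highest for Scn11a, Ano3 and Cacna2d1, with intervals apart from those of the other libraries; for Kcnk2 it was 6.11 to 7.70, against 17.3 to 26.2 over the others. The lowest fold of Ano1 was also in library 6 (24.4 to 56.3).

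Cdx2-Cre acts in the caudal body, so Piezo2 was also compared along the body axis inside each library. Neurons with UMIs of Hox 9 to 11 genes were called caudal, and neurons with none of these but with Hox 3 to 8 UMIs rostral, since Hox genes of higher number mark more caudal segments. This called 6831 caudal and 16980 rostral neurons, 77.1% of all. A caudal neuron without a captured Hox 9 to 11 UMI is called rostral by this rule. Where along the axis Cdx2-Cre begins to act was not measured, so rostral cells are not taken as free of Cre. A ratio near 1 therefore does not speak against a loss of Piezo2 in the caudal body. With class as a stratum, Piezo2 in caudal neurons was 1.08 times that in rostral neurons (range 1.03 to 1.15) and above 1 in each of the 6 libraries. The neuronal reference genes spanned a similar width: Snap25 gave 1.09 (1.06 to 1.12), Scn9a 1.03 (0.988 to 1.05), Tubb3 1.03 (0.962 to 1.04), Syt1 1.01 (0.982 to 1.04), Prph 0.972 (0.959 to 0.990) and Uchl1 0.954 (0.920 to 0.993), and the housekeeping genes Actb 1.00 (0.894 to 1.08) and Gapdh 0.908 (0.875 to 0.949). Piezo1 gave 1.05 (0.389 to 1.79), from few UMIs. Without strata the Piezo2 ratio ran from 0.872 to 1.21.

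The classes differed. In peptidergic-like cells Piezo2 was 1.58-fold higher in caudal cells (1.40 to 1.98), and the interval lay above 1 in 6 of 6 libraries; Snap25 gave 1.14 there (1.07 to 1.23). In A-beta LTMR-like cells it was lower in caudal cells, with a ratio of 0.825 (0.698 to 0.901) and an interval below 1 in 5 of 6 libraries. The reference genes went different ways in that class: Scn9a gave 0.810 (0.643 to 0.872), also with 5 intervals below 1, Snap25 gave 1.1 (0.951 to 1.17) with 5 above 1, and Tubb3 gave 1.02 (0.892 to 1.06). Ratios near 1 were found in C-LTMR-like (1.03, 0.982 to 1.05), A-delta LTMR-like (1.04, 0.970 to 1.18) and proprioceptor-like cells (0.962, 0.819 to 1.21), and Mrgprd nociceptor-like cells gave 1.1 (0.988 to 1.18). With Hox 10 to 11 genes alone marking caudal cells, the A-beta LTMR-like ratio was 0.938 and lay above 1 in 3 of 6 libraries. Within clusters of peptidergic-like cells the ratio was 1.19 (1.07 to 1.46), and in cells thinned to 5000 UMIs it was 1.27 (0.987 to 1.45) and above 1 in 5 of 6 libraries. The comparison says nothing of which library, if any, carries the mutation.

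**Figure D3:**
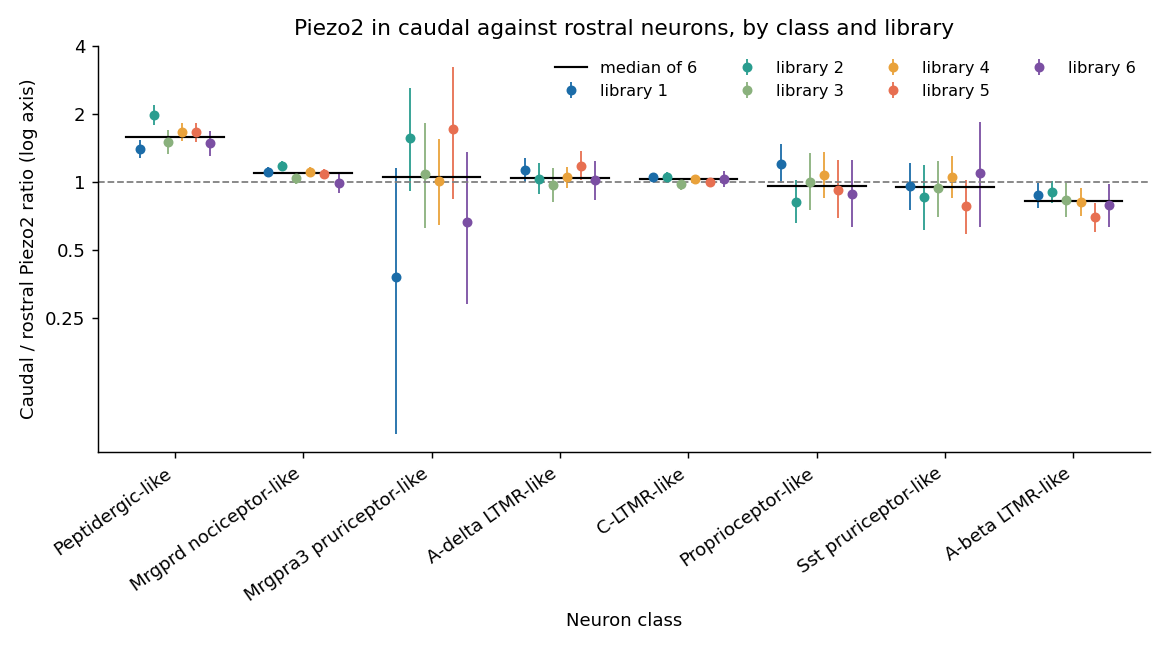
Ratio of Piezo2 in caudal to rostral neurons (vertical log axis, dashed line at 1) in 8 neuron classes (horizontal axis), 1 point per library with its 95% exact interval and a bar at the median of 6. Peptidergic-like cells lie above 1 in 6 of 6 libraries and A-beta LTMR-like cells below 1; Trpm8 thermosensor-like cells, with 0 caudal UMIs in 1 library, are not drawn.

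The libraries were then set against each other, gene by gene, to describe how far they differ. Over all neurons 51 of 6382 genes with a median of at least 20 CPM differed at least 4-fold between the highest and the lowest library. Library 6 was the odd one out for 45 of the 51, and 6 genes were left without it. Xist, the RNA that coats the inactive X chromosome of female cells, was found as 1 and 3 UMIs in libraries 1 and 2 and at 59.1, 52.0, 56.5 and 396 CPM in libraries 3 to 6. It overlaps its antisense gene Tsix, and the strand setting of the counting is not given in the sources used here. The next 7 genes by size of ratio were all lowest in library 6: the ribosomal protein genes Rps2, Rpl29 and Rps18, Rgs5 (a regulator of G-protein signalling that also marks pericytes), Car8 (a carbonic anhydrase-related protein), Serpina11 and Tmsb15b1. Rps2 had 4.53 CPM in library 6 and between 541 and 877 in the others; Rgs5 had 1.07 CPM and between 99.0 and 164. Near-identical copies of Rps2, Rpl29, Rps18 and Tmsb15b1 can share their reads, so those values are uncertain.

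Within classes, 59 of 6146 genes differed in C-LTMR-like cells and 5 without library 6. Xist, Rgs5 and Rpl29 led them: Rgs5 had 3 UMIs in library 6 and between 493 and 633 CPM elsewhere. In A-delta LTMR-like cells 317 of 6156 genes differed, 100 without library 6 and 98 without library 1. Rgs5 and Rps2 were again lowest in library 6, and Cd9, a tetraspanin membrane protein, was highest in library 1 (684 CPM) and lowest in library 5 (8.62 CPM from 6 UMIs). In A-beta LTMR-like cells 187 of 6528 genes differed, 56 without library 6 and 81 without library 1. Rps2 and Rpl29 were found as 0 UMIs in library 6, and the beta-globin gene Hbb-bs, whose paralog can share its reads and whose RNA comes from blood cells, ranged from 3 UMIs in library 2 to 86.5 CPM in library 1. A-delta and A-beta LTMR-like cells of library 1 lay in part in clusters that held none from the other libraries, and C-LTMR-like cells of library 6 were spread over the clusters in other proportions; A-delta and A-beta LTMR-like cells of library 6 were not set apart in this way. Whether these differences follow genotype, animal, day or processing cannot be read from the labels.

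The summed levels of the stress, activity and free RNA lists differed between libraries by a factor of 1.52 or less, and single members by more: Hspa8, a heat shock protein, ranged from 828 to 1712 CPM and Jund, a transcription factor, from 288 to 560 CPM. Immediate early genes, many of which neurons switch on within minutes of activity, summed to a median of 888 CPM over all neurons (632 to 951). Jund, Jun and Bdnf were the most abundant members. Jund alone held a median of 524 CPM, so the sum is not read as activity. Axon injury genes summed to 886 CPM (845 to 1128), led by Cacna2d1, the neuropeptide gene Gal and Hspb1. Heat shock and dissociation genes summed to 3019 CPM (2591 to 3949), led by Hsp90aa1, Hspa8 and Hspe1. Blood and glial genes, meant as a gauge of free RNA in neurons, summed to 1390 CPM (1132 to 1628), led by the myelin gene Pmp22 and by Apoe and Fabp7. Pmp22 had 475, 450 and 599 CPM in libraries 6, 1 and 4. Myelinating Schwann-like cells were 0.200, 2.18 and 7.35% of kept cells there. The sum may therefore not gauge free RNA alone. The sex-linked list differed most, at 105, 130, 175, 154, 172 and 452 CPM in libraries 1 to 6, with Xist highest and the Y-linked gene Ddx3y lowest in library 6 (28.1 CPM, against 44.2 to 59.2 in the others).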

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

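The tests of lower genes without a near-identical copy, of higher genes without introns and of the share of lower genes with a higher copy were chosen after the result was seen, as was the caudal to rostral ratio stratified by cluster.

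Tdtomato, a red fluorescent reporter transgene that no comparison of the report uses, had 430 UMIs in library 6, in 390 of 14361 barcodes (2.72%), and 0 UMIs in libraries 1 to 5, where 3 counts, the most that a count of 0 stands for, would be 0.0194, 0.0299, 0.0188, 0.0147 and 0.0180% of barcodes with a UMI, which does not limit the share of cells expressing it. In library 6 a UMI was found in 36 of 178 proprioceptor-like cells (20.2%, 14.6 to 26.9%), at 103 CPM (80.0 to 131), in 3.06% of the other neurons (6.81 CPM) and in 4.63% of non-neuronal kept cells (24.6 CPM). Median depths were 3358, 4408 and 1757 UMIs. Among the other neurons, Trpm8 thermosensor-like cells held the most, at 26.1 CPM (14.9 to 42.4). Barcodes that were not kept held 22.2 CPM (19.2 to 25.6). The non-neuronal interval, 14.4 to 39.5 CPM, spans that level, so the non-neuronal value is not read as expression. Cre had 2 UMIs, both in library 6. The labels name no reporter, and no explanation was tested.

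The ribosomal protein genes Rps2, Rpl29 and Rps18 and the genes Rgs5 and Car8 were far lower in library 6: over all neurons 16 genes were at least 4-fold lower and 33 at least 4-fold higher there than the median of the other 5 libraries, against 0 to 1 lower and 0 to 3 higher for any other library. For 10 of the 16 lower genes, Rgs5 and Car8 among them, no near-identical copy exists among the features, which argues against shared reads for those; of the 16, 25% had a copy at least 2-fold higher in library 6, such as Rps18-ps3 (102 against 1.22 CPM) and Gm10260 (69.0 against 0.286 CPM) for Rps18. With 1 copy added the gene mostly stayed lower: Rps2 with Gm5786 had 5.64 against 744 CPM, Rpl29 with Gm10709 48.7 against 407, and Rps18 147 against 529 with the first copy and 114 against 528 with the second, while Sft2d1 with Gm12166 came near, at 28.5 against 36.0. Counts moved to 1 copy therefore do not make up the loss of the first 3 genes. Reads that match several genes are left out of counts and would not show in such sums. Shared reads thus stay open for all 6 lower genes with a copy, Tmsb15b1 and Gm26782 among them. Counting of intronic reads is argued against for 11 of the 33 higher genes, which have no introns, and stays open for the rest. Across genes, which are not independent replicates, the ratio followed intron length with a Spearman rho of 0.323. Library 5, compared in the same way, gave 0.431. Median intron length was 5577 bases among the higher genes, those without introns included, 6214.5 among the lower and 22688 among all examined. The higher genes as a set thus did not have long introns. Genes overlapping another gene were 2.01 times as common among the 49 as among all examined. That lies between the 1.5 times set as counting against and the 3 times set as counting for a different annotation. By the annotation used here 16.3% of the 49 overlapped another gene, so overlap may still be a cause for those. For the rest, Rgs5, Car8, Rpl29 and Rps18 among them, it is not settled. They overlap no other gene in GENCODE M21, but the annotation used for counting is not given. Other differences of annotation were not tested. No biological explanation was tested, since the labels put no library in a group.

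Piezo2 was higher in caudal than in rostral peptidergic-like cells in 6 of 6 libraries, with a median ratio of 1.58. A mix of clusters within the class could account for a part, since the ratio within clusters was 1.19 (1.07 to 1.46), which neither removes the difference nor leaves its size. Depth stays open as well: in cells thinned to 5000 UMIs the ratio was 1.27 (0.987 to 1.45). No biological explanation was tested.

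Xist, made by female cells, and Y-linked genes, made by male cells, were both found in libraries 3 to 6. Free RNA or doublets would put both in the same cells. Neurons with an Xist UMI had a Y-linked UMI 0.127, 0.145, 0.125 and 0.0778 times as often as neurons without in libraries 3 to 6, which argues against both. Pooled animals of both sexes may remain as an explanation. No group of the labels allows a test of it.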

How the results depend on the processing

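Leaving out library 6, leaving out library 1 and stratifying by cluster were chosen after the data were seen. Of 589 values of 62 results under 20 alternatives, 484 stayed within the spread between libraries, or within 1.5 times for counts of genes. The other 105 moved further. Direction was not part of this sorting.

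With Hox 10 to 11 genes alone, the Piezo2 caudal to rostral ratio was 1.13 over classes, 0.938 in A-beta LTMR-like and 1.07 in C-LTMR-like cells; without strata it was 1.14. With 2 UMIs needed for a caudal call it was 1.81 in peptidergic-like cells, and within clusters 1.19. Thinned to 5000 UMIs it was 1.27 in peptidergic-like, 1.19 in Mrgprd nociceptor-like and 0.694 in A-beta LTMR-like cells, and with equal weight per cell 0.746 in the last. The cause was not tested. Piezo2 in A-beta LTMR-like cells was 508 CPM at 1.5 times the resolution, 520 with 2000 or more genes and 511 without doublet removal; the cause was not tested. Levels in the other 8 classes moved by less than their spread under every alternative run.

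Counts of genes that differ between libraries moved with the size and level asked for, by construction, and fell without library 6. For all neurons, C-LTMR-like, A-delta LTMR-like and A-beta LTMR-like cells they were 1156, 1166, 3103 and 2369 at 2-fold, 135, 165, 900 and 637 from 5 CPM, and 27, 31, 134 and 84 from 50 CPM. Without library 6 they were 6, 5, 100 and 56, and without library 1 they were 98 and 81 in the last pair of classes. Thinning gave 115, 951 and 482 in the 3 classes, with fewer UMIs per class, and equal weight per cell 786 and 318 in A-delta and A-beta LTMR-like cells. In A-beta LTMR-like cells the count was 114 at 1.5 times the resolution, 91 with 500 or more genes and 113 without doublet removal; the cause was not tested.

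Lower pairs of gene and class numbered 181 after thinning, in part because Trpm8 thermosensor-like cells, with 22 of the 276, were left out; the rest of the cause was not tested. Higher and lower pairs were 183 and 328 at 1.5-fold and 100 and 192 at 3-fold. Of the counts per class, 3 were over 1.5 times larger at 1.5-fold and 7 smaller by as much at 3-fold, 4 of lower genes smaller after thinning, and with 2000 or more genes both counts of Trpm8 thermosensor-like cells smaller. Counts of genes that differ between libraries in the 6 classes not given above were larger in 6 at 2-fold and from 5 CPM, smaller in 6 from 50 CPM and without library 6, smaller in 2 without library 1, larger in 4 after thinning, in 3 with equal weight per cell and in 2 with 2000 or more genes. With equal weight per cell, higher genes were more in Mrgpra3 pruriceptor-like and fewer in Trpm8 thermosensor-like cells. Neurons kept were 24094 with 2000 or more genes, 39287 with 500 or more and 32221 without doublet removal, by construction. The first and second of these filters gave neuron shares of 95.4% and 49.1% and satellite glia-like shares of 1.62% and 31% of kept cells. With 500 or more genes A-beta LTMR-like cells were 6.09% and Mrgprd nociceptor-like cells 26.5% of neurons, and at 1.5 times the resolution Sst pruriceptor-like cells were 9.08%. With equal weight per cell, axon injury genes summed to 1019 CPM and blood and glial genes to 1886 CPM, where shallow cells count for more. No tested value moved with the free RNA profile, 0.5 times the resolution or scaled library totals.

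Depth limits the rare classes: thinning left out 3208 of 5112 neurons in library 6 and left 1 Trpm8 thermosensor-like cell there, so that class was left out of the thinned levels, pairs and ratios. Its share of cells with a Piezo2 UMI, 3.75% (0 to 7.84%) after thinning, rests on 51 to 100 cells in libraries 1 to 5 and that 1 cell. No paired analysis was possible because the labels pair no libraries.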

Other observations

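The caudal shares, the Hox counts and the comparison by Xist were made after the data were seen, and no test was run on any value here.

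Genes of synapses and neuropeptide release also differed between classes. Of 261 pairs of gene and class in a list of 29, 39 were higher and 87 lower by the 2-fold rule in each of 6 libraries. Slc17a7, a vesicular glutamate transporter, reached 459 CPM in proprioceptor-like cells (38.6-fold, 16.9 to 54.7) and 236 CPM in A-beta LTMR-like cells (20.9-fold, 11.3 to 24.8), and Cbln2, a secreted synapse organiser, 567 CPM in proprioceptor-like cells (54.7-fold, 21.4 to 65.9). Slc17a7 and Cbln2 also met the rule for higher in A-delta LTMR-like cells, and Cbln2 in A-beta LTMR-like cells. Sv2a, a synaptic vesicle protein, was higher in C-LTMR-like cells (154 CPM, 4.05-fold, 3.49 to 4.66) and also met the rule in proprioceptor-like cells. In C-LTMR-like cells Bdnf, a growth factor, had 4.13 CPM against 131 in the other classes. Ptprn, a protein of dense-core vesicles, was higher in peptidergic-like (3.73-fold, 3.31 to 4.38) and Sst pruriceptor-like cells (4.42-fold, 3.16 to 4.88). The lowest folds of Slc17a7, of Cbln2 and of Ptprn in Sst pruriceptor-like cells were those of library 6, with intervals below those of the other libraries.

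Proprioceptor-like cells were called caudal most often, at a median of 61.3% of called cells (48.0 to 74.0%), followed by A-beta LTMR-like (46.3%, 43.0 to 49.4%), A-delta LTMR-like (42.7%, 30.8 to 49.4%), Trpm8 thermosensor-like (41.9%, 32.7 to 46.3%) and peptidergic-like cells (36.9%, 34.7 to 39.8%). C-LTMR-like cells were at 27.6% (21.1 to 36.1%), Mrgprd nociceptor-like at 19.1% (18.8 to 21.2%), Sst pruriceptor-like at 18.6% (14.0 to 22.3%) and Mrgpra3 pruriceptor-like at 16.8% (9.72 to 22.2%). Of 14 Hoxd10 UMIs 13, and all 19 Hoxd11 UMIs, were in library 6.

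Xist was found in 0.0161, 0.0625, 18.6, 18.7, 19.2 and 56.1% of neurons in libraries 1 to 6, and a Y-linked UMI in 57.0, 71.4, 57.3, 59.1, 61.4 and 17.9%. With class as a stratum, Piezo2 in neurons with Xist was 1.06, 1.02, 1.00 and 0.996 times that in neurons with Y-linked UMIs in libraries 3 to 6. Single classes lay farther from 1. A-beta LTMR-like cells gave 1.70 (1.35 to 2.14), 1.28 (1.02 to 1.58), 1.07 (0.658 to 1.65) and 1.09 (0.866 to 1.39). These rest on 95, 99, 21 and 194 Piezo2 UMIs in the neurons with Xist. Peptidergic-like cells gave 1.06 (0.912 to 1.23), 0.729 (0.638 to 0.830), 0.890 (0.782 to 1.01) and 0.912 (0.783 to 1.06). The intervals leave out variation between cells, so the ratios are not read as a difference between sexes.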
